A study of Mus musculus with 2 samples.

How the data were processed

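Red pulp macrophages of the mouse spleen, the resident phagocytes that clear aged red blood cells, were profiled from wild-type (WT) mice and from mice lacking SIRPα, an inhibitory receptor of myeloid cells that binds CD47. Per the labels, cells were sorted as F4/80-positive and CD11b-low, cells of 5 mice were mixed for each genotype, globin transcripts were depleted from the RNA, and labelled cRNA was hybridised to 1-colour arrays. Each genotype therefore had 1 array made from 1 pool, and the number of arrays limits the precision of every value. Both arrays lay on 1 slide and were read in 1 scan, so no slide or scan difference separated the genotypes.

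The deposited scanner tables hold spot brightness as intensity on a linear scale, made with Agilent Feature Extraction 11.0.1.1 per the file headers, which also name mouse design 26655 and the mm9 genome build. The processed signal in these tables is the intensity after the software's own background subtraction and spatial detrending, per the file headers. A deposited table of the authors' processed values covers 39485 probes on a log2 scale. These log2 values of the authors had a column median of 4.56 on each array. Set against the scanner signal of the same array, they did not fall at 100.0% of steps between probes ordered by signal (27917 WT probes and 25511 probes of the array labelled SIRPα-KO, all on a single spot and well above background), so the direction of their scale is settled. The normalization steps behind them are not given in the sources used here, and they served as an alternative setting.

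The main values were log2 of the processed signal minus the 75th percentile of the array over non-control spots, which lay at a signal of 100.2 on the WT array and 89.1 on the other. Control spots and spots flagged as non-uniform or as population outliers were left out (190 and 167 of 43020 non-control spots), and no spot was saturated. Spots of 1 probe were averaged. Probes were named by matching the accession of each probe, without its version, to RefSeq transcripts of assembly GRCm38.p6, used for names only; 27234 of 39429 probes matched a symbol, giving 20659 genes. A gene was represented by its probe with the highest mean signal. A gene counted as measured when that probe was well above background on at least 1 array, which held for 15827 genes. For 1673 of these, 1 array was not well above background. The dim side was then set to the higher of its own value and the lowest value among probes well above background on that array, so the fold is a lower bound, written "at least". Where this put the dim side above the measured side, the difference was set to 0.

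With 1 array per genotype no test across samples was possible, and a fixed rule of size was used: a gene was counted as higher or lower when the arrays differed at least 2-fold (1 or more on the log2 scale). All differences are the array labelled SIRPα-KO minus the WT array. The error given after ± is the software's signal error of both arrays carried to the log2 difference. It covers spot measurement only, not animals or pools. For a probe with several spots, the error of an array is the mean error of its single spots, not reduced for their number. As a technical check, 399 probes were spotted 10 times; among those well above background, the median SD of their spots was 0.15 on the WT array (267 probes) and 0.14 on the other (237 probes), on the log2 scale.

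Before the data were examined, 27 gene lists were written, 15 for pathways and 12 for markers of cell types in the spleen. The median difference of a list was placed among 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean signal. A list stands apart here when its median lies below percentile 2.5 or above 97.5. This percentile describes these arrays and is not a p-value; by chance alone 1.35 of 27 lists would be expected outside these limits. The rule for naming genes was fixed at the same time. It took Sirpa; the 12 largest differences each way among genes well above background on both arrays, brighter than the median probe, with the same sign after quantile normalization and after normexp background correction, and with no other measured probe of opposite sign; the 5 largest lower bounds each way; up to 2 genes each way of every list among members at least 2-fold apart; the 2 brightest genes of the macrophage identity list; and Il10, Il6, Tnf, Cd47, Hmox1, Slc40a1, Spic and Vcam1. Predicted genes were counted but not named (88 were at least 2-fold apart). Some genes that the rule took are not reported here; they remain in the counts and list medians.

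The gene and list steps were tested on simulated data. With 200 genes changed and only spot error added, over 14160 genes, 98.0% of genes raised by 1.5 on the log2 scale and 96.0% of those lowered by as much passed the 2-fold rule, as did 100.0% of those changed by 3 either way and 0.043% of unchanged genes. Each change was given to every probe of a gene. The real differences had an SD of 0.62, against a median spot error of 0.21, so these rates check the code and are not error rates of these arrays. Of 200 random lists of 20 genes from the 15827 measured, 5.0% stood apart unshifted, and 97.5% lay under the lower limit after a shift of -0.5. The share unshifted follows from the limits, since these lists came from the same genes as the random lists.

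Alternatives were quantile normalization, scaling to the median of probes well above background, cyclic loess, no scaling, the authors' values, the mean of a gene's probes, its dimmest measured probe, other filters on dim probes, other fold limits, a limit of 2 times the error, 10 bins, and leaving out saturated genes, which removed none. The planned normexp correction on mean signals was not run, because the tables used here hold median signals; normexp with an offset of 50 on median signals took its place and was chosen after the columns were seen. Counts over agreeing probes and list medians without Cxcl10 were added after the data were seen. Work was done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and in R 4.3.3 with limma 3.58.1. Coordinates are not given, because the build of the names differs from that of the arrays.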

Results

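Gene expression in sorted splenic red pulp macrophages was measured on 1 array for WT and 1 array for SIRPα-KO mice, each from a pool of 5 mice. Of 39429 probes, 28184 (71.5%) were well above background on the WT array and 25748 (65.3%) on the array labelled SIRPα-KO. Among genes, 15588 were well above background on the WT array, 14393 on the other and 14154 on both. Across the latter genes, which are not independent replicates, the log2 values of the arrays correlated with Pearson's r = 0.971. The differences had an SD of 0.62 on the log2 scale. No difference has a replicate check.

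The targeted gene was examined first. Sirpa, which encodes SIRPα, had 1 named probe, with a signal of 795 on the WT array and 1006 on the array labelled SIRPα-KO. Its normalised log2 value was 2.99 and 3.50, a difference of 0.51 ± 0.20, or 1.42-fold higher on the array labelled SIRPα-KO. The Sirpa signal thus did not bear out that label. Where the probe lies relative to the deleted part of the gene is not given in the sources used here, and a probe outside the deleted part would check nothing. Every direction below follows the labels alone.

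The design asks how loss of SIRPα changes the transcripts of these macrophages. Chemokine, cytokine and interferon-response genes were lower on the array labelled SIRPα-KO, whose label the Sirpa signal did not bear out. Of 24 measured members of the list of inflammatory cytokines and NF-κB targets, 9 were at least 2-fold lower and 0 at least 2-fold higher. The list median was -0.55 on the log2 scale, at percentile 0.00 of the random lists, whose own median was -0.13. After normexp the median was -0.19, at percentile 2.54, inside the limits. Cxcl10, a chemokine induced by interferons, was 49.1-fold lower, with a signal of 1339 on the WT array and 24.3 on the other (log2 difference -5.62 ± 0.24). Il6, a pro-inflammatory cytokine, was 12.5-fold lower (-3.64 ± 0.21). The other 7 were named after their values were seen. The chemokines Ccl5, Ccl3 and Ccl4 were 3.35-fold, 3.21-fold and 3.11-fold lower, the cytokine Il1b 2.88-fold, the costimulatory receptor Cd40 2.35-fold, and the transcription factor Irf1 2.10-fold lower. A further Irf1 probe, with a signal of 29.8 on the WT array against 222 at the first, differed by -0.22. Ptgs2, the inducible cyclooxygenase, was at least 2.15-fold lower, being not well above background on the array labelled SIRPα-KO. Il1b was read from 8 spots on the WT array, with an SD of 0.11 on the log2 scale, and 10 spots on the other, with an SD of 0.10. Tnf, a cytokine of the same list, differed by 0.02 ± 0.31, with 10 spots per array and spot SDs of 0.21 and 0.23.

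Of 21 measured interferon-stimulated genes, 5 were at least 2-fold lower and 0 at least 2-fold higher, and 18 lay below 0. The list median was -0.49, at percentile 0.11 of the random lists, whose own median was -0.14. Of the 21 genes, 16 lay below that random median. Irgm1 (0.67), Oas1a (0.44) and Xaf1 (0.11) lay above 0. Besides Cxcl10, the gene both lists hold, Oasl1 was 7.77-fold lower (-2.96 ± 0.20), from a signal of 8585 to 982. Ifit1, Ifit3 and Isg15, antiviral effectors named after their values were seen, were 5.80-fold, 4.79-fold and 2.54-fold lower. A further probe of Isg15, with a signal of 12.9 on the WT array, differed by -0.03. Lists for other cell types that make such transcripts did not stand apart: the median was -0.17 for monocyte markers (percentile 40.4), 0.01 for plasmacytoid dendritic cell markers (percentile 75.1) and -0.05 for neutrophil markers (percentile 61.3). Among single markers of these cells, the granulocyte gene S100a8 was 2.35-fold lower. Markers of conventional dendritic cells lay lower, with a median of -0.22 (percentile 11.96), and those of NK cells had a median of -0.17 (percentile 30.2), both inside the limits.

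**Figure D1:**
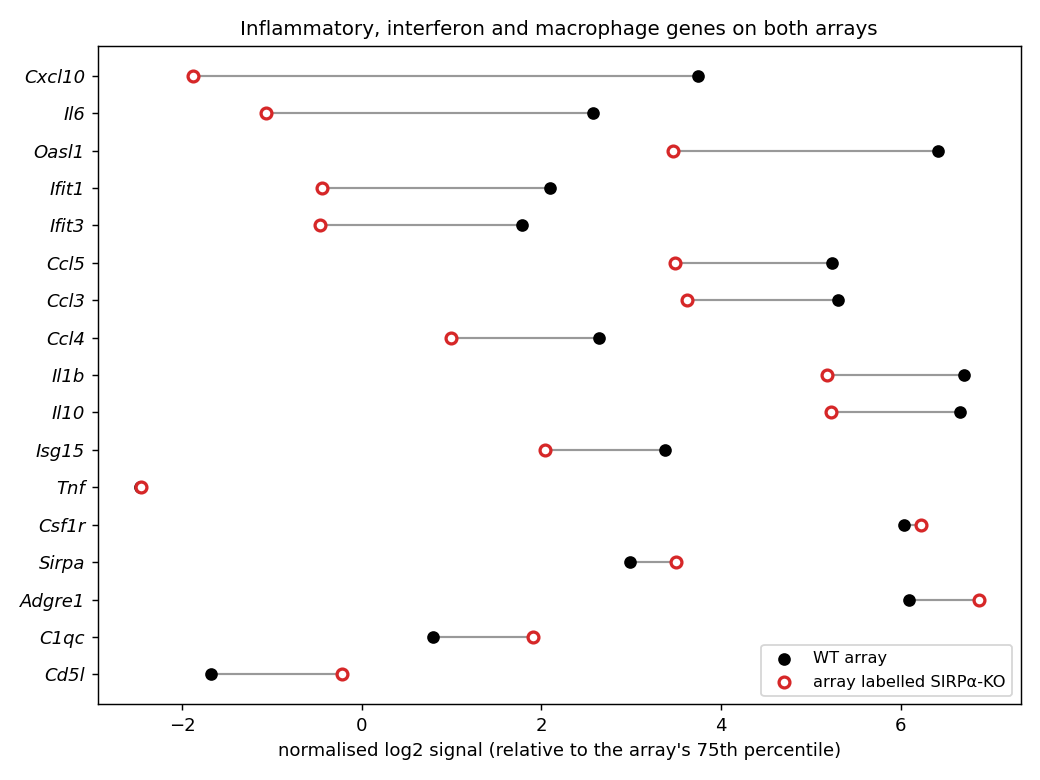
Normalised log2 signal, relative to the 75th percentile of each array, of named genes on the WT array (filled) and the array labelled SIRPα-KO (open), 1 array each. Cxcl10 moved from 3.74 to -1.88 and Il6 from 2.58 to -1.06, while Tnf lay at -2.47 and -2.45, and Cd5l and C1qc were higher on the array labelled SIRPα-KO.

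Genes of macrophage identity were mixed. Of 17 measured members of the red pulp macrophage list, 3 were at least 2-fold higher and 1 lower, with a median of 0.00 (percentile 78.2). That median is the value of a member whose difference was set to 0 by the rule for dim probes. Under the alternatives the median ranged from -0.19 to 0.12 (percentiles 20.5 to 92.9), always inside the limits. Cd5l, a secreted macrophage protein, was 2.74-fold higher (1.46 ± 0.22), and the complement component C1qc, named after its values were seen, was 2.16-fold higher. C1qc was read from 10 spots per array, with SDs of 0.14 and 0.11. The other C1q genes of the list went the other way, C1qa by -0.64 and C1qb by -0.34. Hpgd, which inactivates prostaglandins, was 2.14-fold lower. The brightest members were Adgre1, which encodes the F4/80 antigen used in the sort, at 0.78 ± 0.20, and Csf1r, the receptor for macrophage colony-stimulating factor, at 0.19 ± 0.20. A further Adgre1 probe differed by -0.47. Spic, the transcription factor that red pulp macrophages depend on, differed by 0.17 ± 0.22 and the adhesion molecule Vcam1 by -0.21 ± 0.21, each less than or close to its error.

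Iron handling, the main metabolic task of these cells, showed no common shift: of 23 measured genes 1 was at least 2-fold higher and 2 lower, with a median of -0.06 (percentile 70.0). The iron exporter Slc40a1 differed by -0.15 ± 0.21 and heme oxygenase Hmox1 by -0.32 ± 0.20. The ferroxidase gene Heph was 4.16-fold lower and Aco1, an iron-regulatory protein, differed by -1.32 ± 0.20, while Bach1, a heme-responsive repressor, was 2.22-fold higher. Further Heph probes ranged from -1.12 to 0.29.

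Among 28 measured receptors of phagocytosis, 3 were at least 2-fold higher and 1 lower (median -0.12, percentile 30.9). The scavenger receptor Stab1 was 2.61-fold and the Fcγ receptor Fcgr1 2.35-fold higher, and Cd36 was 3.19-fold lower. The other Fcγ receptor genes of the list went the other way, Fcgr2b by -0.42, Fcgr3 by -0.66 and Fcgr4 by -0.76. In the list around SIRP proteins and inhibitory receptor signalling, 1 of 18 genes was at least 2-fold apart (median -0.09, percentile 65.1). This was the adaptor gene Fyb, 2.64-fold higher, with a further probe at 0.07. Cd47, which encodes the ligand of SIRPα, differed by -0.56 ± 0.23, and its further probe by -0.20. In the list of IL-10 and alternative activation, 3 of 16 genes were at least 2-fold higher and 1 lower (median -0.04, percentile 62.6). Il10, the anti-inflammatory cytokine, was 2.70-fold lower, from 10135 to 3338 over 9 spots per array with SDs of 0.08 and 0.07. The lipid-sensing receptor Trem2 was 2.34-fold higher.

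Genes of the respiratory chain and of lipid handling lay above their random lists, and those of glycolysis did not stand apart. Of 17 measured genes of the mitochondrial respiratory chain, 15 lay above 0, with a median of 0.25 (percentile 98.9), although only Cox7a2, a cytochrome c oxidase subunit, was at least 2-fold higher (2.02-fold). Genes of cholesterol and lipid handling had a median of 0.22 (percentile 98.7), with 12 of 19 above 0. The cholesterol exporter Abcg1 was at least 2.21-fold higher and the fatty acid-binding protein Fabp5 2.05-fold higher, against the lower value of Cd36. Both Abcg1 signals were low, 7.94 on the WT array and 15.6 on the other. Abca1 of the same list differed by -0.15, and 6 of the 19 genes lay below 0. This list fell inside the limits with 4 of its 12 alternatives, reaching percentile 92.5 with the mean of all probes. Medians were -0.11 for glycolysis (percentile 71.6), -0.05 for the lysosome (percentile 69.7), 0.07 for the cell cycle (percentile 84.6), -0.15 for MHC class II (percentile 38.9) and -0.10 for MHC class I presentation (percentile 58.8). In these, the lysosomal proton pump subunit Atp6v0d2 was 7.34-fold lower, the mitotic ubiquitin-conjugating enzyme Ube2c 5.31-fold lower and the peptide transporter Tap2 2.23-fold lower. A further Ube2c probe differed by -0.08. Immediate-early and heat-shock genes, which respond to tissue handling, had a median of 0.01 (percentile 86.0), with Egr2 2.98-fold and Ier3 2.05-fold higher. Both started from low WT signals, of 8.89 and 14.8.

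**Figure D2:**
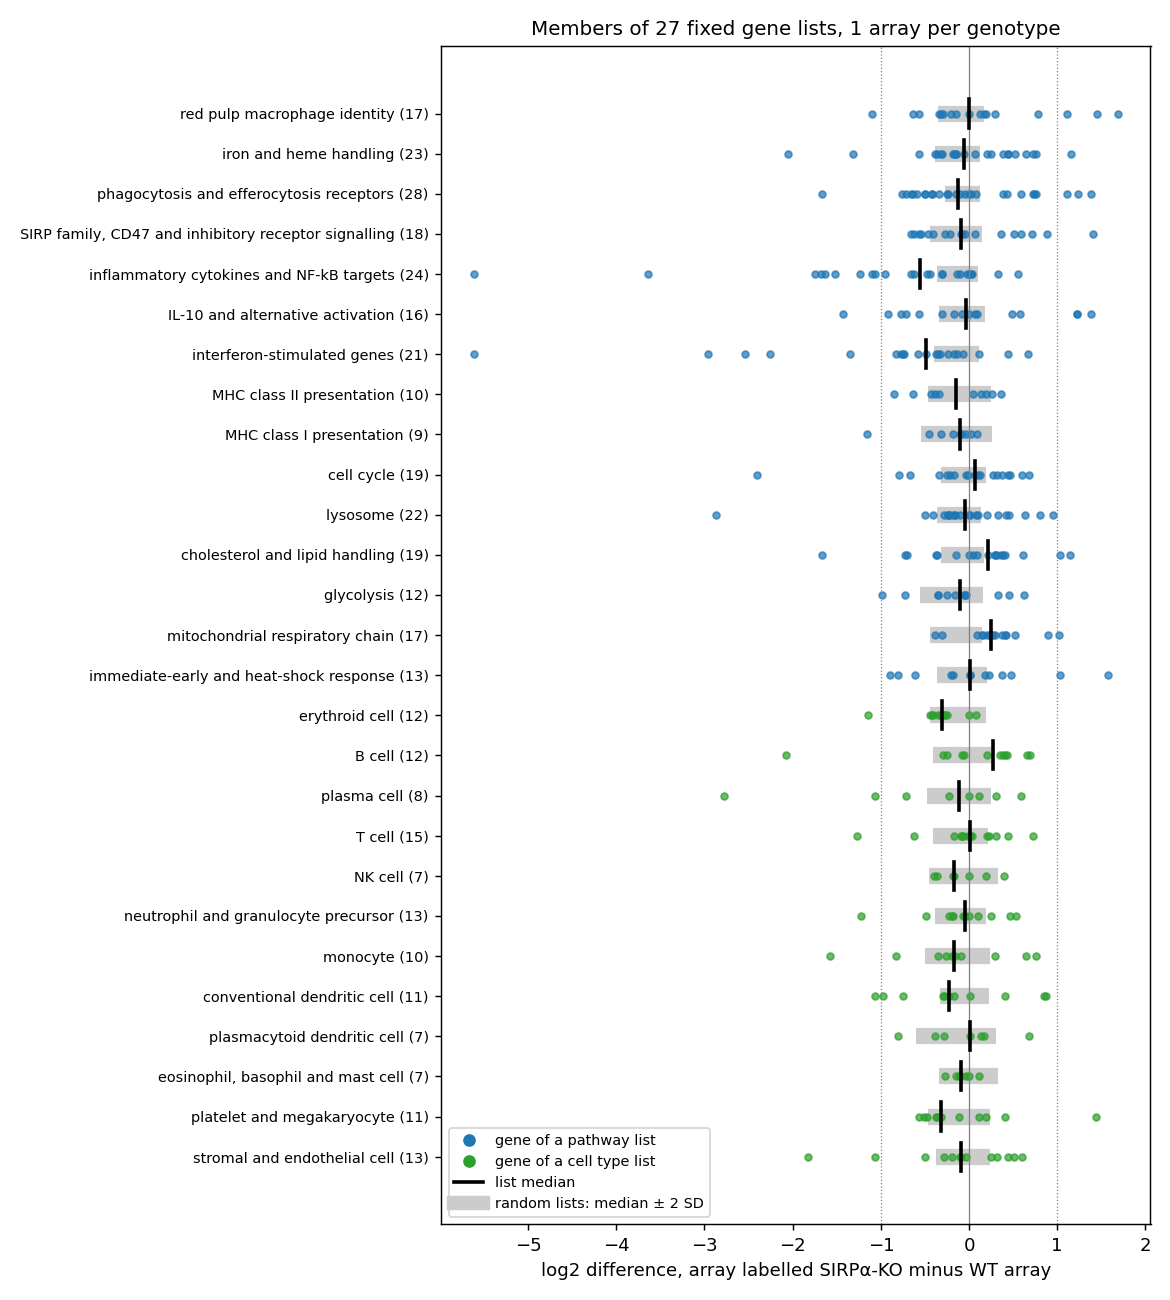
Log2 difference, array labelled SIRPα-KO minus WT array, of each measured gene (points) in 27 gene lists, with the list median (black bar) and the median of random lists of matched signal ± 2 SD (grey). The inflammatory and interferon lists sit lowest against their random lists, with medians of -0.55 and -0.49, and respiratory chain genes sit above theirs, with a median of 0.25.

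Markers of other cells were examined because a sort can carry them. B cell markers had a median of 0.28 (percentile 97.9), yet stood inside the limits with 5 of 12 alternatives, down to percentile 78.3 with no filter on dim probes. In that list the complement receptor Cr2 was 4.21-fold lower, and its further probe differed by 0.31, the other way. No other cell type list stood apart. Medians and percentiles were -0.31 and 10.6 for erythroid cells, -0.12 and 48.3 for plasma cells, 0.01 and 76.2 for T cells, -0.17 and 30.2 for NK cells, and -0.22 and 11.96 for conventional dendritic cells. They were -0.09 and 32.1 for eosinophils, basophils and mast cells, -0.32 and 9.51 for platelets and megakaryocytes, and -0.09 and 44.9 for stromal and endothelial cells. Single markers differed more. The immunoglobulin joining chain gene Jchain was 6.88-fold lower, the plasma cell gene Derl3 2.09-fold lower, the chemokine Ccl19 3.54-fold lower, the endothelial gene Emcn 2.10-fold lower and Cd8b1 of T cells 2.41-fold lower. The Cd8b1 signal was 27895 on the WT array, at percentile 99.1 of measured genes there. Cd8a of the same list differed by 0.015, and its further probe by -0.020. Flt3, a dendritic cell growth factor receptor, was 2.10-fold lower with a further probe at -2.25. The platelet receptor gene Gp1ba was 2.72-fold higher. Further Ccl19 probes differed by -0.01 and 0.04.

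Over all 15827 measured genes, 492 (3.11%) were at least 2-fold higher and 857 (5.41%) at least 2-fold lower on the array labelled SIRPα-KO, and the median difference was -0.08. Of these, 72 and 75 were lower bounds. The split depended on the scaling: higher genes made up 36.5% of those at least 2-fold apart, but 48.5% after quantile normalization, 46.5% after cyclic loess, 47.1% in the authors' values, 20.8% without scaling and 15.0% after normexp. In the brightest 1416 genes measured on both arrays, 259 were at least 2-fold lower and 28 higher.

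The genes that the naming rule took for size were not confined to macrophage or immune genes. The rule left out larger differences where probes of a gene differed in sign or where the other conditions on signal and sign were not met. A gene without a further measured probe passed the condition on probe sign untested. Of the genes taken for size, only Lyst, Gcm1, Dcc, Gab3, Ermn and Akap7 had a further probe. Lower on the array labelled SIRPα-KO, after Cxcl10, were Mgarp (17.4-fold), Il6, Ncln (11.8-fold), Rad1 (11.4-fold), Tmeff2 (10.9-fold), Snhg7 (10.1-fold), Polr3d (9.74-fold), Ghdc (9.54-fold), Eif2a (9.50-fold), Lyst (8.94-fold) and Gpm6a (8.64-fold). Rad1 is a DNA damage checkpoint gene and Lyst a regulator of lysosomal trafficking, whose further probe differed by -0.72. Higher were the integrin subunit Itga1 (13.1-fold), Ermn (8.75-fold), the adaptor Gab3 (7.56-fold), the netrin receptor Dcc (6.84-fold), Pnma2 (6.47-fold), the placental transcription factor Gcm1 (6.23-fold), Akap7 (6.11-fold), Cwc22 (6.04-fold), thrombomodulin Thbd (5.89-fold), Pip4p2 (5.83-fold), Rabgap1 (5.24-fold) and Dst (4.73-fold). Itga1, Thbd and Cwc22 had low WT signals of 9.87, 16.1 and 21.1, against 7.92 for the lowest WT signal well above background, so the size of their folds is uncertain. Further probes of Gcm1 gave 1.38 and 2.69 on the log2 scale. Further probes of Dcc, Gab3 and Ermn gave 0.20, 0.13 and 0.12, and those of Akap7 gave 0.41 and 0.43. Among genes not well above background on 1 array, the lower bounds reached at least 15.1-fold lower for the immunoglobulin-locus gene Adam6a, 6.84-fold for Pnrc1, 5.22-fold for Rbm27, 5.15-fold for Lrrn3 and 4.45-fold for Vmn2r15. They reached at least 4.12-fold higher for Olfr267, 3.95-fold for Maged1, 3.44-fold for Tyrp1, 3.24-fold for Dagla and 3.24-fold for AU018091.

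Different probes of a gene often disagreed. In 2611 genes with more than 1 probe well above background on both arrays, the differences at the brightest and the next probe correlated across genes with r = 0.113. Of 241 such genes at least 2-fold apart at the brightest probe, 22 (9.1%) were also at least 2-fold apart the same way at the next probe, and 142 (58.9%) had the same sign. A further 11549 genes had a single probe well above background on both arrays, Cxcl10, Il6, Oasl1, Ifit1, Ifit3 and Sirpa among them, so their differences have no second probe as a check.

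**Figure D3:**
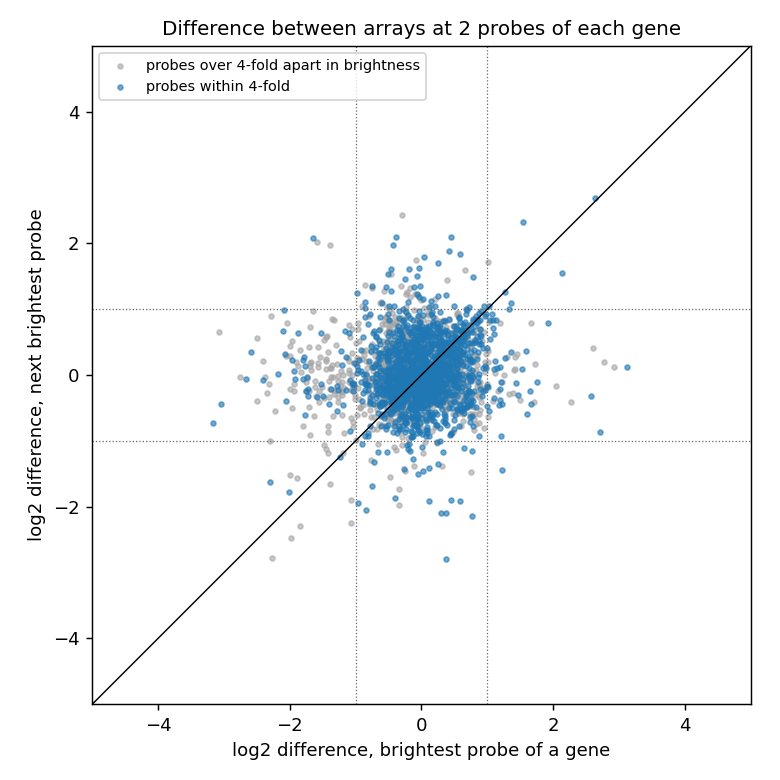
Log2 difference between arrays at the brightest probe (x axis) and the next brightest probe (y axis) of 2611 genes, with pairs within 4-fold in brightness in blue; dotted lines mark 2-fold and the solid line equality. Points spread along both axes rather than along the line of equality, with r = 0.113.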

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

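The probes that could not be named lie outside the comparison of genes. Of 9071 such probes well above background on at least 1 array, 319 had a signal at least 2-fold higher on the array labelled SIRPα-KO than on the WT array, and 460 were at least 2-fold lower. They were flagged because they carry signal above the WT level in data the gene comparison does not use. Their genes are unnamed here, and no explanation was tested.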

How the results depend on the processing

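Normexp on median signals, counts over agreeing probes and medians without Cxcl10 were chosen after the data were seen. The count of genes at least 2-fold higher, 492, was 304 without scaling, 102 after normexp, 877 with no filter on dim probes, 1806 at 1.5-fold and 103 at 3-fold. The count lower, 857, was 1642 with no filter, 2085 at 1.5-fold and 370 at 3-fold. The fold limits and the filter change these counts by their construction. So does leaving out the scaling, which lowers the differences of genes well above background on both arrays by the same amount. That amount is set by the 75th percentiles of 100.2 (WT) and 89.1 (array labelled SIRPα-KO). Normexp added an offset of 50, against median signals of 24.3 and 21.4 on these arrays, which shrinks differences of dim genes by construction. The part of the background correction itself was not tested. The counts stayed within 1.5 times under the other alternatives, among them 676 and 719 after quantile normalization, 478 and 845 with a difference over 2 times its error, and 429 and 698 where all measured probes of a gene agreed. Quantile normalization shared 489 of the higher and 718 of the lower genes. Without scaling the median of all genes was -0.25, against -0.08. The Sirpa difference of 0.51 was 0.80 after quantile normalization and 0.75 in the authors' values, and ranged down to 0.34 without scaling. Cr2 turned to 0.31 at its dimmest probe, a different probe; it was the only named gene at least 2-fold apart that changed sign in these settings. The size of named genes held less well: after normexp 59 of 85 differences moved by more than their error (or 0.3 for a lower bound), and 15 to 18 did so after quantile normalization, cyclic loess, in the authors' values and with other probe choices. The interferon list stood apart in 13 of 13 alternatives (medians -0.66 to -0.31) and the respiratory chain list in 12 of 12 (0.08 to 0.46); for these lists median scaling and no scaling left the percentile where it was, and leaving out saturated genes removed none. The inflammatory list did so in 12 of 13 (-0.72 to -0.19, percentile 2.54 after normexp), and iron handling, inside the limits in the main setting, reached percentile 98.9 with the dimmest probe. Signal over background limits 1673 genes to a lower bound.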

Other observations

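Of the tests below, that of cyclic loess was chosen before its result was seen, and the others after. Genes of olfactory and vomeronasal receptors, a family chosen after the data were seen, were often well above background on these arrays. Of 1326 such genes, 857 (64.6%) were measured by the rule used for all genes, which took 76.6% of all genes. Of these 857, 10.5% were at least 2-fold apart, against 8.5% of all measured genes, and after quantile normalization 9.1% against 8.8%. On the array labelled SIRPα-KO 18 were higher and 72 lower, and lower genes outnumbered higher ones under each scaling, with 20 and 58 after quantile normalization and 21 and 64 after cyclic loess.

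The lower signal of inflammatory and interferon genes on the array labelled SIRPα-KO was set first against a trend of the scaling with signal. After cyclic loess, which removes such a trend, the 44 genes of both lists had a median of -0.35, at percentile 0.00 of random lists. The median that remained argues against the trend as the whole cause. The percentile adds nothing to this, because the random lists were matched on signal and a trend would move both alike. Independent noise of single probes would seldom place the lists this low by itself, which says nothing about any single gene. Differences were shuffled among genes of like signal. The second lowest of the 27 list percentiles, 0.18 for the interferon list in this test, was as low in 12 of 10000 shuffles (0.12%). The shuffle uses the same probe values and matching as the list percentiles. It adds only an allowance for the choice among 27 lists and is not a separate check. The next brightest probe would be a separate check, but it was measured for only 5 genes. It gave a median of -0.22 at percentile 14.3, which does not decide. A smaller share of monocytes, neutrophils and plasmacytoid dendritic cells could contribute and cannot be told apart from a change within macrophages: their 30 combined markers lay at percentile 64.9 (median -0.08), but members went both ways with an SD of 0.52, and the F4/80-positive, CD11b-low gate should remove most such cells. Markers of conventional dendritic cells were not in this set and lay lower (median -0.22, percentile 11.96), so a smaller share of those cells stays untested. Normexp background correction took the inflammatory list inside the limits (percentile 2.54) and left the interferon list outside (-0.37, percentile 0.07). Its offset of 50 shrinks differences of dim genes by construction. How much of the change in the inflammatory list comes from the offset was not tested. Genotype, a difference between the pools such as an infection or stimulation of the WT mice, and the sort stay open as untested, since each genotype had 1 pool.

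The Sirpa signal on the array labelled SIRPα-KO may come from a transcript that keeps the probed part, or from a related transcript; neither was tested. The lower of the signals was 100.4 times the lowest signal well above background, which does not exclude loss of the Sirpa transcript, since a single probe can take up a related one. Exchanged labels cannot be told apart from correct ones, because the difference of 0.51 ± 0.20 is under 2-fold and the place of the probe relative to the deletion is not given. All directions in the comparison carry this limit.

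Large differences at single genes may belong to single probes and not to the gene. For Isg15 and Irf1 the further probes were much dimmer, with WT signals of 12.9 and 29.8 against 1045 and 222. Neither gene is therefore among the pairs of like brightness below, and their further probes do not decide the question for them. Among 92 genes whose brightest probe was at least 2-fold apart and whose next probe lay within 4-fold in brightness, 9.8% of next probes were at least 2-fold apart the same way, and 59.8% had the same sign. Where both probes were also brighter than the median, 16.3% of 43 were. Alternative transcripts and binding of other RNA to a probe would each give this, and no biological explanation was tested.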
